A study of Mus musculus with 18 samples.

How the data were processed

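Spinal cords of 18 mice aged 8 weeks were profiled by RNA sequencing after immunoprecipitation of haemagglutinin-tagged Rpl22 (RiboTag), which brings down ribosome-associated mRNA. The labels give the genotype at Rpl22, Chat-Cre and Gars, from which the 4 groups were formed: Cre P278KY (3 libraries), Cre WT (4), NoCre P278KY (6) and NoCre WT (5). Replicate numbers follow the order of submission within a group and only name mice. The strain background was mixed, and the sex of the mice is not in the labels. The mouse names begin with a number that some mice of different groups share, and its meaning is not given.

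The authors deposited 1 gene table per library with expected counts and TPM, per the file headers those of RSEM gene results. Bowtie2 2.2.0 and RSEM 1.2.12 are named per the submitters' processing notes. The genome build and annotation release are not given in the sources used here. Each table lists 38924 Ensembl genes. The deposited expected counts were whole numbers for 83.0% to 87.4% of the genes and were rounded, which changed no library total by more than 0.00025%. The deposited TPM values (transcripts per 1000000) and effective lengths were not used in any test. Gene positions and biotypes were taken from GENCODE release M21 (GRCm38), which holds 37607 of the gene identifiers, and 1317 had no match there. Genes sharing a symbol were kept apart by identifier.

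Sequencing pools were read from the library descriptions, in which index sequences and sample numbers occur once among the 10 libraries submitted first (pool 1) and start again among the other 8 (pool 2). No pair of libraries was a duplicate. Pearson correlations of log2 CPM within groups ran from 0.956 to 0.976 in Cre P278KY, 0.936 to 0.974 in Cre WT, 0.851 to 0.96 in NoCre P278KY and 0.835 to 0.935 in NoCre WT. Counts from PCR-amplified reads are not independent molecules, so intervals and floors cover counting error only.

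There were 5 comparisons. The genotype difference among Cre libraries used the 7 Cre libraries alone. The enrichment of Cre over NoCre in WT and in P278KY mice, the genotype difference among NoCre libraries and the interaction of genotype with Cre used a fit of all 18 libraries with 4 group means. Each was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, robust dispersions), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. All tests were two-sided. Unless another test is named, an adjusted p of a gene comes from this edgeR test. CPM values of a gene are normalised with the TMM factors of the fit they are given for, so the same libraries differ slightly between the 7-library and the 18-library fit. Log2 values per library used a prior count of 2.

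Before the data were examined, 35 gene lists were fixed, of which 33 were tested with camera from limma 3.58.1 (correlation 0.01), adjusted over the lists, and again with the correlation estimated per list. The fry test was run beside it. The lists covered the integrated stress response (ISR), synthetases, translation stress, chaperones, axon injury, neuron classes, glia, vessels, nerve roots, meninges, blood, muscle, cholesterol synthesis, immediate early genes, interferon, ion channels, motor neuropathy genes, partners of mutant Gars, ribosomal proteins and mitochondrial genes. Reference genes and sex genes were described only. Of the cholinergic motor neuron list, Slc18a3 was not analysed here.

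The genes to be named were also set by rule before the data were examined. For each comparison these were the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM above 1 and no overlap between the groups (not asked of the interaction), leaving out predicted genes, clones, pseudogenes, Xist and Y-linked genes. From each list the up to 4 members with the smallest adjusted p were eligible, and Gars, Rpl22 and Chat were always included. Other genes named are marked as chosen after their values were seen, which also holds for Trib3, Nefh and Spp1 in the Cre genotype difference. A fold against a group with no reads is a lower bound with 3 counts over the group as the floor, and ratios with 1 to 3 reads carry a 95% counting interval.

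The procedure was tested on simulated data with the depth and spread of each comparison, in which 200 genes were changed by 2-fold or 4-fold. For the Cre genotype difference edgeR recovered 20% of the 2-fold and 67% of the 4-fold changes, with 4 false calls among 14318 genes. It recovered 19% and 62% (3 false calls) for the enrichment in WT, 14% and 58% (3) for that in P278KY, 24% and 69% (3) for the NoCre genotype difference, and 3% and 30% (4) for the interaction. False calls were 3.1% to 4.4% of edgeR's calls in the first 4 comparisons and 10.8% for the interaction, where 4 of 20 unchanged lists also had a camera p under 0.05 (0 in the others). They were 17.9% to 29.9% of all calls for DESeq2 and 2.9% to 6.5% for voom. The simulated genes were drawn independently and without pool or sex structure, so the camera result does not cover lists of correlated genes. In the simulated enrichments no genes beyond the 200 differed, so their false-call shares do not carry over to the real enrichments, where far more genes differed.

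The alternatives set before the data were examined were DESeq2 1.42.0, limma voom with sample weights, RLE factors, library size as the only scaling, no low-count filter, a filter at 1 CPM, an adjusted p of 0.10, the pool as a covariate, the log2 CPM of Xist as a covariate, each pool alone, other sets of libraries in the fit, a test of enriched genes only, and leaving out each library in turn. Others were added after the data were seen: the mouse number as a block, library size without ribosomal RNA genes, the oligodendrocyte list as a covariate, and the joint removal of libraries with much ribosomal or glial RNA. The ribosomal RNA genes left out there were mt-Rnr1, mt-Rnr2, Gm26924, AY036118 and Lars2, the last also a member of the mitochondrial synthetase list. For each comparison up to 100 other splits of the same libraries were tested.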

Results

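Ribosome-associated mRNA was measured by RNA sequencing in the spinal cord of 18 mice aged 8 weeks. The RiboTag method was used, in which Cre recombinase switches on a haemagglutinin-tagged form of the ribosomal protein Rpl22, and tagged ribosomes are pulled down with an antibody to the tag together with the mRNA they carry. Cre was driven from Chat, the gene for choline acetyltransferase, the enzyme that makes acetylcholine in motor neurons. The mice had either the dominant P278KY change in Gars, the gene for glycyl-tRNA synthetase, which is mutated in an inherited motor neuropathy, or normal Gars (WT). The 4 groups were Cre P278KY (n = 3), Cre WT (n = 4), and the negative controls without Cre, NoCre P278KY (n = 6) and NoCre WT (n = 5).

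Total counts per library ran from 15461487 to 18944805 in Cre P278KY, 14659532 to 24028695 in Cre WT, 9876870 to 14450218 in NoCre P278KY and 8177817 to 11480463 in NoCre WT. Between 18339 and 22864 genes had at least 1 count in a library. Mitochondrial ribosomal RNA (mt-Rnr1 and mt-Rnr2) took 3.09% ± 1.55 (SD, n = 3) of the counts in Cre P278KY and 1.95% ± 0.95 (SD, n = 4) in Cre WT. It took 29.0% ± 5.82 (SD, n = 6) in NoCre P278KY and 41.5% ± 8.85 (SD, n = 5) in NoCre WT. Protein-coding genes held 23.0% of the counts in NoCre WT replicate 4 and 33.8% in replicate 5 (Wilson 95% intervals 23.0 to 23.1 and 33.8 to 33.8, counting error only), against 37.5% to 60.4% in the 9 other NoCre libraries. By index sequences and sample numbers, which the labels give, 10 libraries were assigned to a first sequencing pool and 8 to a second one. All 3 Cre P278KY libraries were in pool 1, with Cre WT replicates 1 and 2, while Cre WT replicates 3 and 4 were in pool 2. By Xist and Y-linked transcripts, Cre P278KY held 1 male and 2 female mice and Cre WT 2 of each, and both pool 2 Cre WT mice were female. All NoCre mice of pool 1 were male and all of pool 2 female (Xist 0.473 to 0.89 CPM against 180.3 to 1032). In the enrichment in WT and the NoCre genotype difference, pool and sex therefore cannot be told apart. Within pool 1 both Cre WT mice were male and 2 of the 3 Cre P278KY mice female. The Cre genotype difference within pool 1 was thus not balanced for sex.

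The comparison of Cre with NoCre in WT mice asked which mRNAs the tagged ribosomes brought down above unspecific background. Motor neuron transcripts were strongly enriched. All 17 measured genes of the cholinergic motor neuron list were higher in Cre, with a median log2 fold change of 3.82. Chat rose from 7.90 ± 2.92 CPM (normalised counts per 1000000, SD, n = 5) to 122 ± 44 (SD, n = 4), a log2 fold change of 3.95 (adjusted p = 3.14e-10). The choline transporter gene Slc5a7 rose from 22.7 ± 5.68 to 500 ± 119, the transporter-like gene of cholinergic terminals Slc10a4 from 5.60 ± 1.49 to 294 ± 108, and Chodl, a marker of fast motor neurons, from 12.4 ± 2.85 to 427 ± 183. The peptide genes Uts2 (log2 fold change 6.09), Uts2b (5.74), Calca (5.35) and Calcb (4.86) were among the 10 largest rises by the rule for named genes, with Lgals1 (4.83), Sncg (4.66), Fxyd7 (4.56) and Vdr (4.48). Within pool 1 and pool 2 the values were 6.82 and 4.67 for Uts2, 5.86 and 3.71 for Calcb, 5.70 and 3.54 for Lgals1, 5.51 and 3.38 for Fxyd7, and 4.43 and 3.2 for Chat. The neurofilament gene Nefl rose from 1697 ± 95.6 to 15890 ± 3721, Ret from 27.8 ± 7.13 to 316 ± 22.2 and Spp1 from 43.7 ± 5.77 to 508 ± 169. Gars itself rose from 34.1 ± 8.28 to 139 ± 29.3 (log2 fold change 2.03, adjusted p = 3.42e-08), while Rpl22 gave 23.6 ± 4.68 and 32.7 ± 9.75 and did not pass (log2 fold change 0.47, adjusted p = 0.0677), although it passed within pool 1 (0.795, adjusted p = 0.0404) and turned within pool 2 (−0.104, 0.832).

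Transcripts of other spinal cord cells were depleted in the same WT comparison. All 14 microglia genes fell (median log2 fold change −3.37), among them the complement gene C1qb, from 19.9 ± 7.28 to 1.83 ± 0.562 CPM, the microglial receptor gene Csf1r (log2 fold change −3.04), Cx3cr1 (−3.51) and Ctss (−3.65). Of 18 oligodendrocyte genes 17 fell (median −1.76), and the myelin gene Mbp went from 3525 ± 333 to 1018 ± 661. This depletion was smaller in pool 2. Mean log2 CPM of the list was 3.50 and 4.27 in the pool 1 Cre WT libraries and 6.02 and 5.97 in those of pool 2, against 6.986 to 7.145 in NoCre WT. Of 14 astrocyte genes 11 fell and 1 rose (median −1.64), and 11 of 14 vascular genes fell, with Flt1 at −2.80. All 13 mitochondrially encoded protein genes fell (median −3.88), whereas 72 of 77 nuclear genes of the respiratory chain rose (median 1.79) and 58 of 74 ribosomal protein genes rose (median 1.16). By the same rule the 10 largest falls were Rhox8, Cdk15, Pou1f1, Muc19, mt-Rnr2, mt-Nd6, mt-Rnr1, Ccdc144b, Ap1s3 and mt-Nd2, from −5.39 to −4.57. The size of these falls differed between the pools: within pool 1 and pool 2 Rhox8 gave −3.25 and −6.80, Muc19 −2.84 and −6.115, Ap1s3 −2.99 and −5.885, Cdk15 −3.52 and −6.02, Pou1f1 −3.72 and −5.66, and mt-Rnr2 −3.675 and −6.24. The 4 others were also larger in pool 2. In this comparison pool 1 held only males and pool 2 only females, so the difference may be one of pool or of sex. Pool 2 also held NoCre WT replicates 4 and 5, with the lowest protein-coding shares (23.0% and 33.8%), so it may also stem from these 2 libraries. Without them the 25 genes followed in this comparison kept their calls. Adjusted over the list alone, the counts were 17 up for cholinergic motor neuron genes, 14 down for microglia, 17 down for oligodendrocytes, 11 down and 1 up for astrocytes, 12 down for vascular genes and 62 up for ribosomal proteins.

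In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 10227 of 17133 genes between Cre WT and NoCre WT, 4875 higher and 5352 lower in Cre (47.7% higher). Groups did not overlap for 43.2% of the genes tested, against 1.59% by chance. With library size as the only scaling the median of all genes moved from −0.12 to 0.20 and 59.1% of the calls were higher, and with library size taken without ribosomal RNA genes the median was −0.46 and the share 33.7%. By camera, the cholinergic motor neuron list (adjusted p = 7.53e-25), alpha motor neuron list and microglia list (adjusted p = 1.5e-08) held with an estimated correlation (adjusted p = 0.00509, 0.00509 and 0.0288). Other lists lost their call, including oligodendrocyte (adjusted p = 0.292 with an estimated correlation), astrocyte (0.364), vascular (0.192), mitochondrially encoded (0.287), respiratory chain (0.287) and ribosomal protein genes (0.467). Within pool 2 alone (2 against 3 libraries) 4384 genes were called, and mt-Nd2 was no longer among them (log2 fold change −5.60, adjusted p = 0.0664).

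The same comparison in P278KY mice gave a like account. All 17 cholinergic motor neuron genes were higher in Cre (median log2 fold change 4.79; with the CPM filter, 3.40 over 15 genes, against 3.39 in WT), and Chat went from 2.88 ± 0.617 CPM (SD, n = 6) to 105 ± 12.6 (SD, n = 3; log2 fold change 5.19, adjusted p = 7.22e-12). The largest rise among the genes open to naming was that of Fgf21, which encodes a secreted metabolic stress hormone, from 0.818 ± 0.654 to 104 ± 33.8 (log2 fold change 7.16, adjusted p = 4.68e-09). Other large rises were those of Uts2 (6.73), Calcb (5.86), Slc10a4 (5.73), Cdsn (5.56), Prph (5.45), Arhgap36 (5.13), Chodl (5.08), Slc5a7 (5.00) and Calca (5.00). Gars rose from 35.0 ± 5.20 to 274 ± 23.1 (log2 fold change 2.97, adjusted p = 1.62e-10), and Rpl22 rose from 18.7 ± 3.49 to 34.7 ± 0.0751 (0.89, adjusted p = 0.00204). The integrated stress response (ISR) list, genes regulated by ATF4 and CHOP when the initiation factor eIF2alpha is phosphorylated, had 27 members up and 1 down of 36 (median 2.14), and all 23 cytosolic tRNA synthetase genes rose (median 2.05). In WT mice the ISR list had 9 up and 7 down of 36 (median 0.13, which turned to −0.01 with RLE factors and −0.14 with library size without ribosomal RNA genes; camera adjusted p = 0.513), and 21 of 23 synthetase genes rose (median 1.23, adjusted p = 1.59e-07, but 0.287 with an estimated correlation).

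All 14 microglia genes, all 18 oligodendrocyte genes and all 14 vascular genes fell in the P278KY comparison (medians −3.81, −3.14 and −3.28). All Cre P278KY libraries were in pool 1, so these medians cannot be set directly against those of WT over both pools. Mbp went from 3110 ± 296 to 352 ± 118 CPM. The 10 largest falls by that rule included the skeletal muscle genes Myh1 (log2 fold change −5.82), Tnnt3 (−4.98), Myh2 (−4.98), Myl1 (−4.91) and Tnnc2 (−4.83), and also Ly86, Car3, Serpind1, Lcat and mt-Nd2. The test called 10183 of 17133 genes, 4840 higher and 5343 lower, and 56.2% of the genes tested did not overlap, against 2.38% by chance. Adjusted over the list alone, the ISR count was 27 up and 1 down and the synthetase count 23 up. The lists whose camera calls held with an estimated correlation were ISR (adjusted p = 1.05e-05), cholinergic (0.00117), alpha (0.00741) and gamma (0.0289) motor neurons, cytosolic synthetases (0.0357), microglia (0.0204) and heat shock proteins (0.0224), whereas the oligodendrocyte list gave adjusted p = 0.164 and the vascular list 0.117. Within pool 1 alone Myh2 missed the threshold (−5.54, adjusted p = 0.0537). With the mouse number as a block all 5 muscle genes were lost, from Myh1 (−3.65, adjusted p = 0.13), Tnnt3 (−2.50, 0.0916) and Myh2 (−2.61, 0.183) to Myl1 (−2.26, 0.187) and Tnnc2 (−2.05, 0.376).

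**Figure D1:**
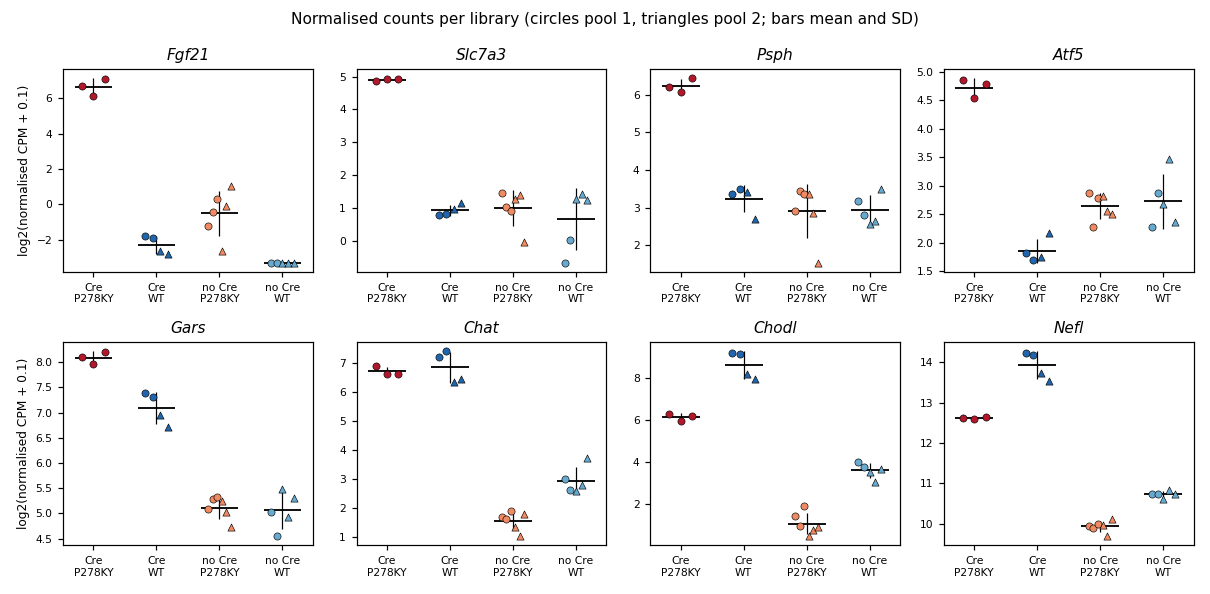
Normalised CPM on a log2 axis for 8 genes in each of the 18 libraries, by group, with circles for pool 1, triangles for pool 2, and the mean and SD of each group. Fgf21, Slc7a3, Psph and Atf5 lie higher in all 3 Cre P278KY libraries than in all 4 Cre WT libraries, and Chodl and Nefl lie lower.

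The comparison of Cre P278KY (n = 3) with Cre WT (n = 4) asked how RNA in the Cre immunoprecipitates, enriched for cholinergic neurons, differed with the Gars genotype. Of the 342 genes called, 209 were enriched in Cre over NoCre libraries (mean of both genotypes). Changes of the others are not shown to come from these neurons. Genes of the ISR rose together: 24 of the 37 measured members rose and none fell, with a median log2 fold change of 1.84. Fgf21 (Ensembl gene ENSMUSG00000030827, GRCm38 chromosome 7, 45613886 to 45615490) went from 0.120 ± 0.0741 CPM (SD, n = 4) to 113 ± 34.8 (SD, n = 3), a fold of 1014 (log2 fold change 9.99 ± 0.412 SE, adjusted p = 3.88e-06; within pool 1, 9.20). The serine synthesis gene Psph rose from 10.2 ± 1.95 to 82.5 ± 9.29 (log2 fold change 3.02, adjusted p = 9.4e-05), the arginine and lysine transporter gene Slc7a3 from 1.95 ± 0.340 to 32.6 ± 0.827 (4.05, adjusted p = 3.44e-05), and Cth, which makes cysteine from cystathionine, from 1.01 ± 0.637 to 19.3 ± 3.11 (4.29). The transcription factor gene Atf5 rose from 3.83 ± 0.817 to 28.8 ± 3.33 (2.90, adjusted p = 0.000247).

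Further ISR genes with large rises were the stress regulator Nupr1, from 2.25 ± 2.46 to 45.6 ± 2.43 CPM (log2 fold change 4.30, adjusted p = 0.0105; within pool 1, 5.80), and Phgdh, the first enzyme of serine synthesis, from 5.62 ± 4.39 to 56.4 ± 7.48 (3.29, adjusted p = 0.0227; within pool 1, 4.93). Other ISR genes were chosen after their values were seen. Adm2 had 866 reads in the 3 Cre P278KY libraries and none in the 4 Cre WT libraries, at least 427-fold higher with 3 counts over the group as the floor. Gdf15 had 609 reads against 3, a ratio of 290 with a counting interval from 98.6 to 1410. Chac1, which breaks down glutathione, rose from 23.3 ± 6.69 to 71.1 ± 5.15 CPM (1.61, adjusted p = 0.00800), and Trib3 did not pass (3.31, adjusted p = 0.138). The list's median was 1.84 with Adm2 at its bound as well, which could not have differed, as Adm2 lies above the median either way. Adjusted over the list alone, 32 of the 37 genes rose. The list held by camera (adjusted p = 1.74e-99) and with an estimated correlation (adjusted p = 0.000282), and within pool 1 alone (3 against 2 libraries) 32 members rose, with a median of 2.21. Some of these calls were lost when 1 library was left out. Without Cre P278KY replicate 1, 2 or 3 or Cre WT replicate 3, adjusted p for Phgdh was 0.108, 0.0865, 0.0728 and 0.0646. Nupr1 missed the threshold without Cre P278KY replicate 1 (0.0513) or 2 (0.0501) or Cre WT replicate 3 (0.0647), Chac1 without Cre P278KY replicate 3 (0.0527). Phgdh also missed it with library size as the only scaling (0.0877) and, like Nupr1, without a low-count filter (0.138 and 0.0799). Nupr1 was lost with the mouse number as a block (3.70, adjusted p = 0.0702).

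Of the 23 cytosolic tRNA synthetase and scaffold genes, 8 rose and none fell, with a median log2 fold change of 0.62. Wars, which charges tryptophan tRNA, rose from 130 ± 32.3 CPM (SD, n = 4) to 365 ± 13 (SD, n = 3; log2 fold change 1.49, adjusted p = 0.00539). Rars went from 51.4 ± 8.20 to 128 ± 21.5 (1.31, adjusted p = 0.00767), Iars from 73.1 ± 12.9 to 176 ± 13.4 (1.26, adjusted p = 0.00767) and Lars from 41.0 ± 8.46 to 96.3 ± 11.3 (1.23, adjusted p = 0.0126). Gars (ENSMUSG00000029777, chromosome 6, 55038007 to 55079500) rose from 148 ± 26.5 to 298 ± 21.5, a log2 fold change of 1.01 ± 0.187 SE (adjusted p = 0.0219). Within pool 1 the Gars change was 0.81 (adjusted p = 0.0247) and the list median 0.36, with 8 members up. The 17 mitochondrial synthetase genes had no member past the threshold by edgeR (median −0.03, which turned to 0.01 with library size only and 0.02 with library size without ribosomal RNA genes), nor had the 13 genes of eIF2alpha kinases and ribosome rescue (median −0.01, turning to 0.06 with library size only and 0.05 without ribosomal RNA genes).

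Adjusted over the list alone, 14 cytosolic synthetase genes rose, as did 1 of the rescue genes, and no mitochondrial synthetase gene passed. The cytosolic synthetase list passed by camera (adjusted p = 4.64e-11) but not with an estimated correlation (adjusted p = 0.356), and the mitochondrial and rescue lists did not pass (0.951 and 0.609). Several synthetase calls were lost when 1 library was left out. Over all alternatives the log2 fold change stayed between 0.814 and 1.29 for Gars and between 1.013 and 1.504 for Lars. Without Cre P278KY replicate 1, 2 or 3, adjusted p for Gars was 0.151, 0.0816 and 0.109, and for Lars 0.0695, 0.0621 and 0.0742. Gars was also lost without Cre WT replicate 4 (0.0611), Iars without Cre P278KY replicate 1 (0.0608) or 2 (0.0501) and with library size only (0.0996), and Rars without Cre P278KY replicate 1 (0.0713) or 3 (0.0518). Wars kept its call in all 21 alternatives.

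Motor neuron markers moved less uniformly. Chat (ENSMUSG00000021919, chromosome 14, 32408203 to 32465989) gave 115 ± 16.3 CPM in Cre P278KY and 129 ± 41.5 in Cre WT and did not pass (log2 fold change −0.17 ± 0.258 SE, adjusted p = 0.811; within pool 1, −0.52, adjusted p = 0.120). The tagged gene Rpl22 (ENSMUSG00000028936, chromosome 4, 152325742 to 152334071) gave 37.9 ± 1.03 and 34.8 ± 9.03 (0.12, adjusted p = 0.842; within pool 1, −0.167, 0.635). Chodl (ENSMUSG00000022860, chromosome 16, 78930948 to 78951733) fell from 453 ± 181 to 78.6 ± 9.75 (−2.53 ± 0.323 SE, adjusted p = 0.00320) and the neurofilament light chain gene Nefl from 16920 ± 3399 to 6899 ± 135 (−1.30, adjusted p = 0.0103). The alpha motor neuron markers Rbfox3, from 170 ± 21.1 to 80.4 ± 17.1 (−1.08, adjusted p = 0.0223), and Vipr2, from 37.9 ± 6.57 to 14.9 ± 5.4 (−1.34, adjusted p = 0.0403), also fell. The potassium channel gene Kcnj14 fell from 140 ± 26.3 to 61.8 ± 5.93 (−1.18, adjusted p = 0.0143). Nefm (−1.34, adjusted p = 0.0603), Nefh (−0.75, adjusted p = 0.157), Calca (−1.90, adjusted p = 0.0512), Spp1 (−0.55, adjusted p = 0.306) and Mmp9 (−0.62, adjusted p = 0.285) did not pass.

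By list, 2 of 17 cholinergic motor neuron genes fell and none rose (median log2 fold change −0.62), 3 of 6 alpha motor neuron genes fell (−0.85), and 1 of 16 ion channel genes of excitability fell (−0.50). Of 8 gamma motor neuron genes none passed by edgeR (median 0.87), and of these Esrrb gave 17.1 ± 0.765 CPM against 9.31 ± 2.29 (0.87, adjusted p = 0.0950) and Htr1f 5.04 ± 2.23 against 1.64 ± 0.743 (1.60, adjusted p = 0.119). Adjusted over the list alone, 6 cholinergic, 3 alpha and 3 excitability genes fell, and 7 gamma genes rose and 1 fell. The camera calls (adjusted p = 0.00011, 7.96e-05, 0.00015 and 0.00180 for cholinergic, alpha, excitability and gamma) were lost with an estimated correlation (adjusted p = 0.503, 0.102, 0.356 and 0.356). Within pool 1, 9 of 17 cholinergic genes and 5 of 6 alpha genes fell, 1 alpha gene rose and 3 of 8 gamma genes rose (medians −0.87, −0.95 and 0.99). Without Cre P278KY replicate 1, 2 or 3, adjusted p for Nefl was 0.0953, 0.0865 and 0.0768, for Vipr2 0.101, 0.121 and 0.107, and for Kcnj14 0.0875, 0.0890 and 0.0967. Rbfox3 was lost without Cre P278KY replicate 1 (0.154) or 3 (0.136) or Cre WT replicate 1 (0.0521) or 4 (0.0582), and Vipr2 also without Cre WT replicate 1, 3 or 4 (0.0702, 0.0583 and 0.0850). Rbfox3 (0.280), Vipr2 (0.272) and Kcnj14 (0.0813) missed the threshold with library size only, and Vipr2 (0.437) and Kcnj14 (0.248) in the fit of all 18 libraries. Vipr2 missed it with library size without ribosomal RNA genes as well (0.0693).

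Several neuronal stress and injury genes rose. Atf3, an injury-induced transcription factor gene, went from 0.342 ± 0.154 CPM to 5.45 ± 3.06 (log2 fold change 3.97, adjusted p = 0.00704), the growth cone gene Gap43 from 72.3 ± 12.7 to 154 ± 16.0 (1.09, adjusted p = 0.0163), and the neuropeptide gene Adcyap1 from 22.8 ± 3.33 to 53.8 ± 19.0 (1.24, adjusted p = 0.0354). These were 3 of the 13 measured axon injury genes, of which 4 rose and 1 fell when adjusted over the list alone (median 0.29, camera adjusted p = 0.00967, 0.404 with an estimated correlation; within pool 1, 3 up and a median of 0.36). The cell cycle inhibitor gene Cdkn1a rose from 20.1 ± 17.0 to 217 ± 47.6 (3.42, adjusted p = 0.0443; within pool 1, 5.05). Its CPM was 6.13 and 6.96 in the pool 1 Cre WT libraries and 25.4 and 41.8 in those of pool 2, and its call was lost with library size only (adjusted p = 0.0882) and without a low-count filter (0.18). Of 12 heat shock genes, Hspe1 rose (1.41, adjusted p = 0.0479) and Cryab fell from 119 ± 10.1 to 33.1 ± 1.32 (−1.85, adjusted p = 0.000517), with 5 up and 1 down over the list alone (median 0.68, camera adjusted p = 0.0739). Of 12 activity-dependent immediate early genes none passed by edgeR, and 7 rose over the list alone (median 0.95, camera adjusted p = 0.000116, 0.356 with an estimated correlation). No gene of the 18 ER chaperones passed (median 0.25, adjusted p = 0.0415, 0.630 with an estimated correlation). Leaving out Cre P278KY replicate 1 ended the calls of Atf3 (adjusted p = 0.0572), Gap43 (0.141), Adcyap1 (0.212), Cdkn1a (0.148) and Hspe1 (0.201). Without Cre P278KY replicate 2 adjusted p was 0.0565 for Gap43, 0.126 for Cdkn1a and 0.143 for Hspe1, and without replicate 3 it was 0.0825, 0.109 and 0.193, and 0.139 for Adcyap1. Among the Cre WT libraries, leaving out replicate 1 ended Gap43 (0.0514) and Adcyap1 (0.0570), replicate 2 Adcyap1 (0.0681), Cdkn1a (0.0734) and Hspe1 (0.0516), replicate 3 Adcyap1 (0.0573), Cdkn1a (0.146) and Hspe1 (0.0522), and replicate 4 Adcyap1 (0.0791) and Hspe1 (0.0919). Adcyap1 was also lost with library size only (0.0889) and Hspe1 with RLE factors (0.0522).

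By the rule for named genes (mean log2 CPM above 1), the largest rises outside the ISR list were those of Cdsn, which encodes an adhesion protein of skin, from 0.136 ± 0.102 to 41.2 ± 0.743 CPM (log2 fold change 8.34, adjusted p = 7.01e-05), and Cox6a2, a heart and muscle subunit of cytochrome oxidase, from 0.305 ± 0.250 to 28.7 ± 6.59 (6.68, adjusted p = 9.11e-05). The purinergic receptor gene P2rx3 rose from 0.923 ± 1.10 to 28.4 ± 8.55 (4.86, adjusted p = 0.0102; within pool 1, 7.21) and Avil from 0.844 ± 0.920 to 17.3 ± 1.00 (4.35, adjusted p = 0.0216). Both belong to the sensory neuron list, in which 2 of 4 measured genes rose (3 up and 1 down over the list alone; median 3.11, mean 0.61, camera adjusted p = 0.00180, 0.189 with an estimated correlation; within pool 1, 2 up and 1 down). Another member, Scn10a, had 0 reads in Cre P278KY and 203 in Cre WT, 165 of them in replicate 4 and 11 to 14 in each other library, and did not pass (adjusted p = 0.0877). The growth factor gene Vegfa rose from 14.1 ± 3.37 to 35.0 ± 1.24 (1.31, adjusted p = 0.0128). Without Cre P278KY replicate 1, 2 or 3, adjusted p for Avil was 0.0892, 0.0865 and 0.0791 and for Vegfa 0.0931, 0.0789 and 0.0640. Avil was also lost without Cre WT replicate 2 (0.0666), with the pool covariate (4.88, 0.05, just over the threshold) and with the mouse number as a block (4.05, 0.278), P2rx3 without Cre P278KY replicate 2 (0.0582) or Cre WT replicate 3 (0.0647), and both without a low-count filter (0.104 and 0.0780). Vegfa missed the threshold with library size only (0.0989).

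Among the largest falls, Cd24a (ENSMUSG00000047139, chromosome 10, 43578284 to 43584265), which encodes a surface glycoprotein, went from 855 ± 194 CPM (SD, n = 4) to 53.8 ± 11.7 (SD, n = 3; log2 fold change −3.99 ± 0.272 SE, adjusted p = 9.11e-05). Itm2a, which encodes a membrane protein, fell from 77.9 ± 25.6 to 6.67 ± 0.856 (−3.54, adjusted p = 0.000382), Arhgap9 from 8.59 ± 1.54 to 0.613 ± 0.153 (−3.77) and the kinase gene Wnk4 from 9.94 ± 2.83 to 0.832 ± 0.225 (−3.58). The immunoglobulin gene Ighm fell from 71.8 ± 13 to 10.2 ± 6.33 (−2.80, adjusted p = 0.00419), and the remaining large falls were Aldh1a7 (−3.27), Pon3 (−2.99), Pla2g3 (−2.89), Il1f9 (−2.81) and Mrvi1 (−2.70; within pool 1, −2.06). Ahnak2, chosen after its values were seen, fell from 679 ± 64.5 to 246 ± 61.9 (−1.46, adjusted p = 0.00690). Aldh1a7 was lost without any 1 of Cre P278KY replicates 1, 2 and 3 or Cre WT replicates 1, 2 and 3 (adjusted p from 0.0573 to 0.157), Pon3 without Cre P278KY replicate 1 (0.0728) or 2 (0.0582), and Mrvi1 without Cre P278KY replicate 1 (0.0582) or 3 (0.0541). Ahnak2 (0.0594), Aldh1a7 (0.0813), Mrvi1 (0.0752) and Ighm (0.05, just over the threshold) were lost with library size only, and Aldh1a7 with the mouse number as a block (0.131).

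Markers of other cell types were mostly not past the threshold between Cre P278KY and Cre WT. No gene passed by edgeR among 18 oligodendrocyte (median log2 fold change −1.46), 6 oligodendrocyte precursor (−0.96), 14 astrocyte (−1.02), 13 vascular (−1.18), 9 meningeal (−2.80), 10 microglia (−0.10), 2 ependymal (−0.57), 7 red blood cell (−0.71, mean −0.34, though camera ranked the list up), 10 inhibitory (0.23) and 7 excitatory interneuron genes (−0.72). Mbp gave 382 ± 118 CPM against 1113 ± 764 (adjusted p = 0.223). Of 7 Schwann cell genes Prx fell from 10.1 ± 3.44 to 3.10 ± 0.933 (−1.71, adjusted p = 0.0338) and Pmp22 from 361 ± 26.0 to 200 ± 38.7 (−0.85, adjusted p = 0.0464). Within pool 1 the medians were 0.05 for oligodendrocyte, 0.40 for astrocyte, 0.21 for vascular, −0.56 for meningeal, −0.55 for Schwann, −3.07 for skeletal muscle, 0.135 for oligodendrocyte precursor, 0.024 for microglia, −0.197 for ependymal and 0.189 for red blood cell genes (1 up). Inhibitory interneuron genes had 2 up there (median 0.727) and excitatory ones 2 up and 1 down (−0.109). The 8 skeletal muscle genes had a pooled median of −2.55, with none past the threshold over all genes and 7 down over the list alone. The camera calls for oligodendrocyte (adjusted p = 0.000109), astrocyte (0.00660), vascular (0.0415), meningeal (0.0152), Schwann (0.00876) and muscle genes (1.09e-05) were lost with an estimated correlation (adjusted p = 0.630, 0.634, 0.634, 0.634, 0.503 and 0.356). Prx was lost without Cre P278KY replicate 1, 2 or 3 or Cre WT replicate 4 (adjusted p = 0.189, 0.152, 0.0742 and 0.0768) and with library size only (0.130). Pmp22 was lost without any 1 of the 7 libraries (adjusted p from 0.0544 to 0.246) and with library size only (0.350), and both missed the threshold in the fit of all 18 libraries (0.0588 for Prx, 0.253 for Pmp22) and with library size without ribosomal RNA genes (0.0511 and 0.0797).

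In all, edgeR's quasi-likelihood test called 342 of 14717 genes between Cre P278KY and Cre WT, 179 higher and 163 lower (52.3% higher), of which 152 and 147 differed by more than 2-fold. At an unadjusted p under 0.05 there were 2377 genes. Groups did not overlap for 16.7% of the genes tested, against 5.7% by chance. With library size as the only scaling 148 genes were called, 62.8% of them higher. Leaving out Cre P278KY replicate 1, 2 or 3 left 95, 121 and 126 calls. Within pool 1 there were 1343 calls. Of the 33 lists tested, camera called 18, and ISR alone held with an estimated correlation.

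**Figure D2:**
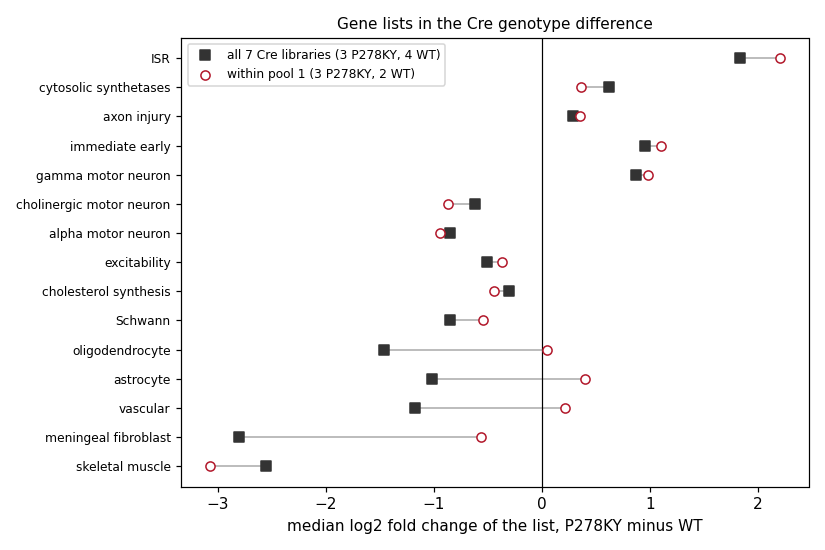
Median log2 fold change of 15 gene lists between Cre P278KY and Cre WT, over all 7 Cre libraries and within pool 1 (3 against 2 libraries). The ISR median is 1.84 over all libraries and 2.21 within pool 1, and the oligodendrocyte median is −1.46 and 0.05.

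The comparison of NoCre P278KY (n = 6) with NoCre WT (n = 5) asked whether the genotype changed the background RNA. Motor neuron transcripts were lower in the mutant background. Chodl fell from 12.4 ± 2.85 CPM (SD, n = 5) to 2.11 ± 0.873 (SD, n = 6; log2 fold change −2.55 ± 0.276 SE, adjusted p = 5.94e-05). Ahnak2, a large scaffold protein gene, fell from 73.5 ± 23.4 to 25.6 ± 4.86 (−1.52, adjusted p = 0.00062), Chat from 7.90 ± 2.92 to 2.88 ± 0.617 (−1.45, adjusted p = 0.0339) and Nefl from 1697 ± 95.6 to 980 ± 91.7 (−0.79, adjusted p = 0.0470). Gars gave 35.0 ± 5.20 and 34.1 ± 8.28 (0.04, adjusted p = 0.976; within pool 1, 0.425, and within pool 2, −0.249) and Rpl22 18.7 ± 3.49 and 23.6 ± 4.68 (−0.33, adjusted p = 0.745). Fgf21 had 53 reads in the 6 NoCre P278KY libraries and none in the 5 NoCre WT libraries, at least 11.7-fold higher with 3 counts over the group as the floor, and did not pass (adjusted p = 0.267).

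Of 17 cholinergic motor neuron genes 3 fell and none rose between the NoCre groups (9 down adjusted over the list alone; median log2 fold change −0.82), and the list held by camera (adjusted p = 8.98e-22) and with an estimated correlation (adjusted p = 0.00418). Its median was −0.91 within pool 1 and −0.93 within pool 2. Of 6 alpha motor neuron genes 1 fell (2 over the list alone; median −0.23, turning to 0.03 with library size only; adjusted p = 0.0184 with an estimated correlation). The ISR list had no gene past the threshold by edgeR and 1 up over the list alone, with a median of 0.29 (adjusted p = 0.00431 with an estimated correlation; 0.26 within pool 1 and 0.17 within pool 2). The 74 ribosomal protein genes (median −0.26) and 77 respiratory chain genes (−0.32) had no gene past the threshold and turned to 0.20 and 0.18 with library size only. Their camera calls (adjusted p = 5.65e-07 and 7.17e-07) were lost with an estimated correlation (adjusted p = 0.966 for both), and their medians were 0.10 and 0.15 within pool 1 and −0.67 and −0.71 within pool 2.

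The 4 genes above, all lower, were the only ones of 17133 that edgeR called, with 1163 at an unadjusted p under 0.05. DESeq2 called 28 genes, 17.9% of them higher, and library size as the only scaling 2 genes, 50.0% of them higher, with the median of all genes moving from −0.01 to 0.35. There Ahnak2 (−1.105), Chat (−1.07) and Nefl (−0.43, all adjusted p = 0.71) lost their calls and the motor neuron median was −0.43. Chodl and Ahnak2 kept their calls whichever library was left out. Chat was lost without NoCre WT replicate 1 or 5 (adjusted p = 0.117 and 0.107) or NoCre P278KY replicate 1, 2, 3, 4 or 5 (0.0976, 0.114, 0.0510, 0.0848 and 0.116). Nefl was lost without NoCre WT replicate 1, 3, 4 or 5 (0.181, 0.0770, 0.107 and 0.0792) or NoCre P278KY replicate 1, 2, 3, 4 or 5 (0.214, 0.177, 0.144, 0.108 and 0.116). Within pool 1 the log2 fold changes were −2.47 for Chodl, −1.42 for Ahnak2, −1.12 for Chat (not called, adjusted p = 0.375) and −0.80 for Nefl, and within pool 2, where none of the 4 passed, −2.82, −1.53, −1.76 and −0.79. With the mouse number as a block Ahnak2 (−1.13, adjusted p = 0.225), Chat (−0.885, 0.999) and Nefl (−0.578, 0.999) were lost and the motor neuron median was −0.406. Chat and Nefl were lost with the fit of these 2 groups alone (0.234 and 0.169) and without NoCre WT replicates 4 and 5 (0.576 and 0.619), or those and NoCre P278KY replicate 6 (both 0.245). Chat was lost by voom (0.172), and Nefl with RLE factors (0.0678), the Xist covariate (0.0834), no low-count filter (0.0586) and library size without ribosomal RNA genes (0.13).

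The interaction of genotype and Cre asked which genotype differences in the Cre libraries went beyond those of the background. ISR genes again rose together: 14 of 36 measured members were higher and none lower (25 up adjusted over the list alone; median log2 interaction 1.55; camera adjusted p = 4.07e-41, and 7.49e-09 with an estimated correlation). Atf5 had an interaction of 3.01 (adjusted p = 0.000271), Psph 2.92 and Slc7a3 3.72 (both adjusted p = 0.000589), and Ddit3, which encodes CHOP, 2.88 (adjusted p = 0.000589). Other large rises were those of the collagen receptor gene Ddr2 (2.94), Fam129a (3.26), Arap3 (3.37), Mdfic (3.71), Phgdh (3.12) and Cdkn1a (3.03). The interaction within pool 1 was smaller for Slc7a3 (2.62) and Mrvi1 (−2.11) and larger for Cdkn1a (4.64), Phgdh (4.26), Fam129a (4.075), Mdfic (4.37), Wnk4 (−4.39) and Itm2a (−4.34). Cd24a (−3.61) and Itm2a (−3.73) were lower (both adjusted p = 4.76e-06), as were Wnk4 (−3.32), Pla2g3 (−3.31), Pon3 (−3.13), Ighm (−2.92) and Mrvi1 (−2.76). Wars (1.72, adjusted p = 0.00789) and Rars (1.36, adjusted p = 0.0119) were the 2 of 23 cytosolic synthetase genes that passed (12 up over the list alone; median 0.91; camera adjusted p = 2.8e-12, 0.346 with an estimated correlation). Leaving out Cre P278KY replicate 1 ended the calls of Cdkn1a (adjusted p = 0.0514), Mdfic (0.051), Wnk4 (0.0566), Mrvi1 (0.051), Pon3 (0.123) and Rars (0.0571), and leaving out replicate 3 those of Mdfic (0.0635), Mrvi1 (0.0538) and Rars (0.067). Pon3 was also lost without Cre P278KY replicate 2 (0.109) or Cre WT replicate 2 (0.054). Wars was lost within pool 1 (0.985, adjusted p = 0.0733), where Ighm was lost too (−2.76, 0.0888), and with library size only (1.36, 0.375). Of these genes Cd24a, Itm2a and Gdf15 (9.65, chosen after its values were seen) kept their calls with library size only, and Gdf15 was lost without NoCre WT replicate 4 (0.171), within pool 1 (adjusted p = 1) and without NoCre WT replicates 4 and 5 and Cre WT replicates 3 and 4 (0.0763). In that last fit Wars was lost too (0.0546), Cdkn1a without a low-count filter (0.0563), and Mrvi1 (0.0513) and Rars (0.0972) with library size without ribosomal RNA genes.

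Gars (0.94, adjusted p = 0.149; within pool 1, 0.328, 0.558), Chat (1.24, adjusted p = 0.145; within pool 1, 0.543, 0.347) and Rpl22 (0.42, adjusted p = 0.684; within pool 1, −0.134) had no interaction past the threshold. The cholinergic motor neuron list had none past it over all genes and 1 up over the list alone (median 0.16, turning to −0.09 with library size only; adjusted p = 0.0900). Oligodendrocyte genes had none past it over all genes and 9 down over the list alone (median −1.43, adjusted p = 1.32e-08, 0.382 with an estimated correlation). In pool 1 the library means of this list (log2 CPM) overlapped, at 3.37 to 4.41 in Cre P278KY and 3.50 and 4.27 in Cre WT. Those of Cre WT replicates 3 and 4, in pool 2, were 6.02 and 5.97. In all edgeR called 112 of 17133 genes, 59 higher and 53 lower (52.7% higher). The share higher was 39.9% with DESeq2 and 72.2% with library size without ribosomal RNA genes. With library size only, 5 genes were called and the median of all genes was −0.32. Within pool 1 there were 405 calls.

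**Figure D3:**
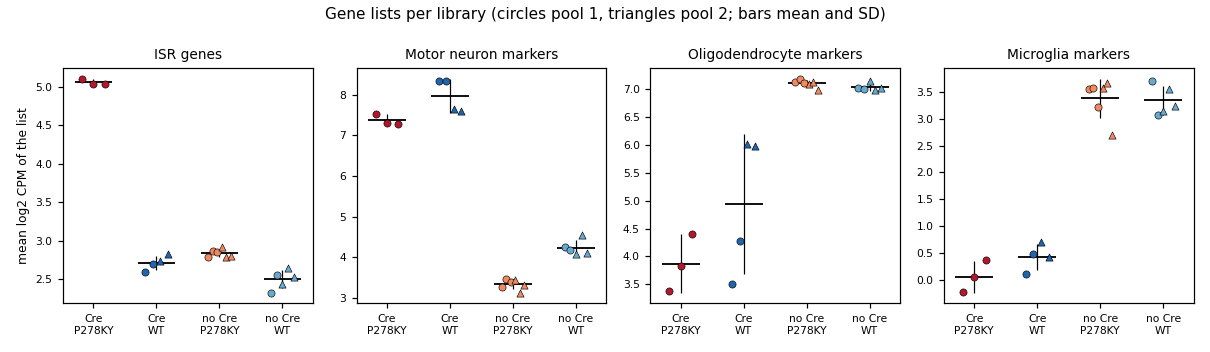
Mean log2 CPM of the ISR, cholinergic motor neuron, oligodendrocyte and microglia lists in each library, by group, with circles for pool 1 and triangles for pool 2. The 2 Cre WT libraries of pool 2 have the highest oligodendrocyte means among the 7 Cre libraries.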

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

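All tests of explanations in this part, and the bounds they were held to, were chosen after the results were seen.

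In 4 of the 56 groups of 4 to 10 libraries tested for a library far from the others, such a library was found. Chance gives about 1 in 20 groups, or 2.8 of 56. Cre P278KY, with 3 libraries, was too small for this test. Its replicate 3 had a mitochondrial ribosomal RNA share of 4.88%, against 2.23% and 2.16% in replicates 1 and 2. Malat1 took 1.85% of the counts there, against 0.407% and 0.404%. Cre WT replicate 2 had a mitochondrial ribosomal RNA share of 3.36% (Wilson 95% interval 3.35 to 3.37, counting error only), against 1.36% to 1.69% in the other 3 Cre WT libraries. Cre WT replicate 4 had 5.90 CPM of Nupr1, against 0.745 to 1.47, and Cre WT replicate 2 had 15.3 CPM of Pon3, against 6.93 to 8.06. NoCre WT replicate 5 had 12.9 CPM of Chat, against 5.87 to 7.86 in the other 4 NoCre WT libraries.

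Genotype differences that themselves differed between Cre and NoCre libraries (the interaction test) numbered 112 genes, and the ISR list had a median log2 interaction of 1.55. By the rule for named genes (mean log2 CPM above 1), which leaves out scarcer genes such as Gdf15, the genes with the largest interactions were Slc13a4 (−4.31), Mxra8 (−3.82), Fbln1 (−3.74), Itm2a (−3.73), Cd24a (−3.61), Wnk4 (−3.32), Pla2g3 (−3.31), Pon3 (−3.13), Ighm (−2.92) and Mrvi1 (−2.76) among those lower in Cre. Among those higher they were Slc7a3 (3.72), Mdfic (3.71), Arap3 (3.37), Fam129a (3.26), Phgdh (3.12), Stc2 (3.04), Cdkn1a (3.03), Atf5 (3.01), Ddr2 (2.94) and Psph (2.92). Several of these calls were lost when 1 library was left out. Without Cre P278KY replicate 1 adjusted p was 0.0514 for Cdkn1a, 0.0566 for Wnk4, 0.051 for Mdfic and Mrvi1, and 0.123 for Pon3. Without replicate 3 it was 0.0635 for Mdfic and 0.0538 for Mrvi1, and Pon3 was also lost without Cre P278KY replicate 2 (0.109) or Cre WT replicate 2 (0.054). Slc13a4 was lost without Cre P278KY replicate 1, 2 or 3 (0.123, 0.101 and 0.067) or Cre WT replicate 4 (0.0544). Fbln1 was lost without Cre P278KY replicate 1, 2 or 3 (0.0776, 0.144 and 0.12), Cre WT replicate 3 or 4 (0.0646 and 0.0723), NoCre P278KY replicate 5 (0.0696), or NoCre WT replicate 2 or 4 (0.0668 and 0.0728). Mxra8 was lost without any 1 library (0.0542 to 0.2) except Cre WT replicates 1 and 2 and NoCre WT replicate 3. Stc2 was lost without any 1 library (0.059 to 0.152) except Cre WT replicate 1, NoCre P278KY replicate 6 and NoCre WT replicates 2, 3 and 4. Within pool 1 Slc13a4 (−2.33, adjusted p = 0.111), Mxra8 (−1.73, 0.237) and Ighm (−2.76, 0.0888) were not called and Fbln1 was −2.59 (0.0258). Mxra8 was lost with the pool covariate as well (−3.25, adjusted p = 0.105). With library size without ribosomal RNA genes Slc13a4 (0.063), Fbln1 (0.0761), Mxra8 (0.105) and Mrvi1 (0.0513) were lost. With library size only, Itm2a and Cd24a alone of these 20 kept the call. Without NoCre WT replicates 4 and 5 and Cre WT replicates 3 and 4, Slc13a4 (0.206), Mxra8 (0.306), Fbln1 (0.0898) and Stc2 (0.154) were lost. So were Mxra8 (0.079) and Fbln1 (0.065) without a low-count filter, Mxra8 (0.0505) and Stc2 (0.0524) with RLE factors, and Stc2 with the Xist covariate (0.0542).

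Other splits of the same libraries into groups of the same sizes were run for each comparison. For the interaction, of 100 splits, the real one included, 5 called as many genes (112 in the real split, 180 in the highest other) and 6 gave an ISR median as far from 0 (1.55 against 1.72 in size), shares that do not exclude chance. Of these 100 splits, however, 9 set 3 Cre WT libraries against the other Cre libraries and so hold most of the real contrast turned round. Among the 91 others, a choice made after the splits were seen, 3 called as many genes (highest other 127) and 1, the real one, gave such a median (highest other 0.917). Whether the shares are under 0.05 thus depends on how turned splits are counted. All 4 other splits with as many genes, 2 of them turned, placed Cre WT replicates 3 and 4, the Cre libraries of pool 2, together in the smaller Cre group. Mean log2 CPM of the ISR list was 5.04 to 5.11 in Cre P278KY, 2.59 to 2.82 in Cre WT and 2.32 to 2.92 in the NoCre libraries. Within pool 1 the interaction had 405 calls and an ISR median of 1.78. For the Cre genotype difference 1 of 35 splits, the real one, called as many genes (342 against 7) and 1 gave an ISR median as far from 0 (1.84 against 1.76). This is the smallest share that 35 splits allow. The 1.76 came from a turned split, Cre WT replicates 1, 3 and 4 against the other Cre libraries. Shares were not adjusted over the comparisons. For the enrichment in WT it was 1 of 100 splits for the calls (10227 against 6310) and 1 for the motor neuron list median (3.82 against 3.60). In P278KY it was 1 of 84 splits for the calls (10183 against 0) and 1 for that median (4.79 against 3.90). For the NoCre genotype difference 2 of 100 splits called as many genes, with 14 calls in another split against 4, and 3 gave a motor neuron median as far from 0 (0.82 in size, since it was −0.82, against 0.89), so the shares were under 0.05. The split with 14 calls, which put NoCre WT replicates 1, 4 and 5 with NoCre P278KY replicates 3, 5 and 6, has several times the real count. Whether it reflects a structure of these libraries was not tested.

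Lower oligodendrocyte markers in Cre P278KY than in Cre WT (median log2 fold change −1.46) have a candidate explanation in more glial RNA in the 2 Cre WT libraries of pool 2. Within pool 1 the median was 0.046 (3 against 2 libraries), so the values this explanation needs are there. An effect of the genotype stays open: the difference of library means within pool 1 was −0.016, with a 95% interval from −1.551 to 1.52 that covers the −1.07 of all 7 libraries. Sex stays open too: females exceeded the male by 0.751 within Cre P278KY and the males by 2.11 within Cre WT, where both pool 2 mice were female. Pool, sex and genotype therefore cannot be told apart for these markers.

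Lower motor neuron markers in NoCre P278KY than in NoCre WT (median −0.82) might come from Cre reads counted in NoCre libraries of the same pool. Within pool 1 a test covered reads from Cre P278KY libraries. There, 9 genes abundant in Cre P278KY and near 0 in Cre WT had 46 reads in NoCre WT (upper limit 61.4). The whole Chat level of these NoCre WT libraries (8.15 and 5.67 CPM by library size) would need 188.4 with all pool 1 Cre libraries contributing alike. Such carry-over as the source of all Chat reads there is thus argued against. Yet NoCre P278KY libraries of pool 1 also had Chat (3.32 to 4.18 CPM), and the excess over them would need fewer reads. The test was not set for this excess, so it cannot decide the difference between genotypes. Reads from Cre WT libraries would leave almost no trace in these genes, so that source stays open. The other pool held no Cre P278KY library, so the test cannot decide there either, where the motor neuron median was −0.93. Less neuronal RNA of every type is argued against by the interneuron lists, whose median was −0.028 (95% interval over 18 resampled members −0.277 to 0.171). That interval covers spread between genes, not between mice. Library means (log2 CPM) overlapped for inhibitory genes, at 4.321 to 4.531 in NoCre P278KY and 4.098 to 4.658 in NoCre WT. So did those of excitatory genes (2.246 to 3.408 and 2.837 to 3.046), but not of motor neuron genes (3.131 to 3.464 and 4.086 to 4.542). NoCre WT replicates 4 and 5, with the most mitochondrial ribosomal RNA, are argued against as the source by a motor neuron median of −0.719 without them. An effect of the genotype on motor neuron RNA in whole cord stays open as a hypothesis, as do dissection and cord level, which were not tested. With the number that begins the mouse names as a block the median was −0.406, so a part shared by mice of the same number stays open too. NoCre mice of both genotypes shared a number only across pools, which also differ in sex. These were NoCre P278KY replicates 2 and 3 with NoCre WT replicate 3, and NoCre WT replicate 2 with NoCre P278KY replicate 6.

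Higher Avil and P2rx3 in Cre P278KY than in Cre WT could come from dorsal root ganglion tissue left on the cord. This is argued against: reads per 1000000 of the other 6 listed ganglion markers summed to 1.26 ± 0.044 (SD, n = 3) in Cre P278KY and 4.66 ± 6.28 (SD, n = 4) in Cre WT (14.1 in replicate 4, 1.36 to 1.68 in the other 3), while Avil and P2rx3 together gave 47.9 and 1.87. In Cre WT replicate 4 and NoCre P278KY replicate 4 these other markers exceeded Avil and P2rx3 (14.1 against 5.13 and 20.6 against 8.48), so ganglion RNA at the mutant level of Avil and P2rx3 would bring far more of them. Of the 6, Scn10a had 0 reads in Cre P278KY, but Prrxl1 was higher there (1.07 to 1.24 CPM against 0.147 to 0.414). Expression of both genes by the cholinergic neurons of mutant mice stays open as a hypothesis, untested at the level of cells.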

How the results depend on the processing

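The tests chosen after the data were seen are the mouse number block, the scaling without ribosomal RNA genes, the oligodendrocyte covariate and the joint removals of libraries. The ISR median in the Cre genotype difference stayed between 1.62 and 2.26, and no alternative turned the ISR medians of the Cre genotype difference and the interaction, or the cholinergic motor neuron medians of the enrichments and the NoCre genotype difference. For 126 called gene results followed through the alternatives, 2646 of 2950 values kept the call, 304 lost it and 0 reversed. These are not the same as the results named in the text. In the enrichments they were the largest changes, cholinergic motor neuron genes, Gars, Rpl22 and Chat, so genes such as C1qb and Mbp were not followed. The Cre genotype difference (342 genes) gave 660 at an adjusted p of 0.10, 972 with DESeq2, 879 with voom, 148 with library size only, 1677 with the pool covariate, 1343 within pool 1, 1156 with the oligodendrocyte covariate and 1664 with the mouse number block. That block sets Cre P278KY replicates 1 and 3 against Cre WT replicates 3 and 4, which also differ in pool. With all Cre P278KY libraries in pool 1, the pool covariate leaves the same contrast as pool 1 alone. Both gave an ISR median of 2.205 with 32 members up, so they are not 2 separate checks. The enrichment in WT (10227) gave 4384 within pool 2 and 9121 within pool 1. Pool 1 held still fewer libraries of these groups, so library number alone does not account for the 4384. No count for P278KY moved by 1.5 times. The NoCre genotype difference (4) gave 28 with DESeq2, 2 with library size only, 2 with the mouse number block (1 of them shared), 7 without ribosomal RNA genes, 36 within pool 1, 2 without NoCre WT replicates 4 and 5, and 2 without these and NoCre P278KY replicate 6. Within pool 2 there were 3, all higher, and 0 were shared with the 4. The interaction (112) gave 196 at an adjusted p of 0.10, 381 with DESeq2, 564 with voom, 5 with library size only, 54 without ribosomal RNA genes, 405 within pool 1 and 193 without NoCre WT replicates 4 and 5 and Cre WT replicates 3 and 4. At an adjusted p of 0.10 the threshold itself explains the change. For the others the cause was not tested, though DESeq2 also made more false calls on simulated data (22.7% of its calls against 4.4% for the Cre genotype difference).

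Leaving out 1 library gave 95 to 324 genes in the Cre genotype difference (95, 121 and 126 without Cre P278KY replicates 1, 2 and 3). The NoCre genotype difference ranged from 2 (without NoCre WT replicate 1 or 5 or NoCre P278KY replicate 1, 2, 3 or 5) to 6 (without NoCre P278KY replicate 6). The interaction ranged from 41 to 250: 41, 60 and 48 without Cre P278KY replicates 1, 2 and 3, and 250, 64 and 70 without Cre WT replicates 1, 3 and 4. Lists called by camera went, with the correlation estimated per list, from 18 to 1 in the Cre genotype difference, 18 to 3 and 21 to 7 in the enrichments in WT and P278KY, 5 to 3 in the NoCre genotype difference and 15 to 1 in the interaction.

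All 342 genes called in the Cre genotype difference were called by DESeq2 and voom, 334 of them with RLE factors, 139 with library size only and 329 within pool 1. Of 5825 genes enriched in Cre and tested, 286 were called when tested alone, 209 of which were among the 342. Scaling moved the median of all genes by over 0.1 in places. With library size only it went from −0.12 to 0.20 in the enrichment in WT, to 0.354 in the NoCre genotype difference and −0.322 in the interaction. Without ribosomal RNA genes it was −0.456 and −0.34 in the enrichments and 0.113 in the interaction, and with RLE factors −0.26 and −0.25 in the enrichments. Changes are therefore relative to the rest of the RNA in a library. Leaving out the low-count filter changes the genes tested and not the scaling, and gave medians of −0.839 and −0.626 in the enrichments. No paired analysis was possible because replicate numbers only name mice. The number that begins the mouse names is shared by some mice of different groups, and a block on it gave the counts above and moved no other count by 1.5 times. No value for pool 2 alone could be given for the Cre genotype difference, the enrichment in P278KY or the interaction, since no Cre P278KY library is in pool 2. At this depth and spread, the test found 20% of simulated 2-fold and 67% of 4-fold changes in the Cre genotype difference, and 3% and 30% in the interaction, so a gene not called is not shown to be unchanged.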

Other observations

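No test in this part was planned for the genes near Gars or for Sowahc, which were looked at after the results were seen, while the lists were set before.

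Metabolic and organelle lists had few genes past the threshold between Cre P278KY and Cre WT. Of 24 cholesterol synthesis genes none passed by edgeR over all genes and 5 fell when adjusted over the list alone (median log2 fold change −0.30, camera adjusted p = 0.0018, 0.356 with an estimated correlation). Pmvk, a kinase of the mevalonate pathway, gave 26.6 ± 2.50 CPM (SD, n = 3) against 53.0 ± 13.9 (SD, n = 4; −0.99, adjusted p = 0.0577). Within pool 1 the cholesterol median was −0.44, with 5 members down. Of 74 ribosomal protein genes none passed (median −0.14, adjusted p = 0.613), and of 75 nuclear respiratory chain genes Cox6a2 alone (median −0.14, adjusted p = 0.717). Within pool 1, 5 ribosomal protein genes fell (median −0.52), and 17 respiratory chain genes fell and 1 rose (−0.58). The 13 mitochondrially encoded protein genes had a median of 0.35, with none past the threshold (adjusted p = 0.0375, 0.661 with an estimated correlation; 0.10 within pool 1).

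Among 21 genes of inherited motor neuropathy Nefl alone passed, with 2 up and 3 down over the list alone (median −0.11, adjusted p = 0.235; within pool 1, 5 down and a median of −0.31). Of 6 measured genes for partners of mutant Gars, Vegfa alone passed (median −0.02, turning to 0.04 with library size only and 0.03 without ribosomal RNA genes; adjusted p = 0.409). None of 3 genes of other cholinergic neurons passed over all genes and 1 rose over the list alone (median 0.73, adjusted p = 0.0766). It was Nos1, which makes nitric oxide, with 107 ± 16.1 CPM against 64.5 ± 11.2 (0.73, adjusted p = 0.0969). None of 10 interferon response genes passed (median −0.42, adjusted p = 0.609; 0.32 within pool 1), nor did any of 9 reference genes (median 0.18) or 5 sex genes (median −0.41).

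Fgf21 reads in NoCre P278KY replicates 1 to 6 numbered 5, 11, 15, 1, 10 and 11, against 0 in each of the 5 NoCre WT libraries. The symbol Sowahc, chosen after its values were seen, belongs to 2 Ensembl genes (ENSMUSG00000071286 and ENSMUSG00000098188), and in each library at most 3 reads fell on the less used one. In the Cre libraries the used gene followed the genotype, so both were among the 342 calls, while in the NoCre groups both forms occurred within a genotype. Their summed reads were 54 to 188 in Cre P278KY and 63 to 274 in Cre WT. Of 91 tested genes within 10 Mb of Gars on chromosome 6, 2 were called between Cre P278KY and Cre WT (2.2%), against 339 of 14625 elsewhere (2.32%; Fisher exact p = 1).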
